A study of Homo sapiens with 3 samples.

How the data were processed

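Per the labels' protocols, total RNA of U937 cells was made into 3 Illumina TruSeq RNA libraries, 1 for each of R280I DMSO, R280I ATO and wild-type ATO. The submitters' processing notes name cutadapt 1.9.1, HISAT2, HTSeq and the genome build hg38, without their order or settings, so the annotation and whether strand was used in counting were not given in the sources used here. Reads of overlapping genes on opposite strands and of near-identical copies are therefore uncertain. The values deposited by the authors were FPKM per gene, per the file headers, although RPKM was expected when the design was fixed. The treatment of the values is the same for both units. The columns carried abbreviated names, in which an A after the p53 form was read as ATO from the titles of the libraries, an inference that every comparison rests on.

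The table held 60612 genes by Ensembl identifier, of which 102 had no value. Symbols were taken from a name table for 60401 identifiers and from GENCODE 29 for 187, and 24 stayed without one. Coordinates, gene types and exon lengths are those of GENCODE 29 on GRCh38, which holds 58394 of the identifiers. That release may differ from the annotation the authors counted with.

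Depth was recovered from the low values. For many genes, FPKM multiplied by the summed exon length fell on steps of 1 read, which gave denominators of about 18365800 (R280I DMSO), 18031700 (R280I ATO) and 17645800 (wild-type ATO). Within a tolerance of 0.02 reads, 46.5%, 46.1% and 51.0% of genes came out as whole reads, and 65.5%, 64.5% and 69.9% of those with up to 100 reads. Where the gene model differs from the authors', the estimated count is approximate, and whether reads or fragments were counted is not known. Estimated reads were rounded and used for 95% exact (Clopper-Pearson) intervals of the fold between 2 libraries, which cover counting error alone since reads without molecular identifiers are not independent molecules. For a gene listed at 0, a floor of 3 reads was used.

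Ratios were taken as log2((FPKM + 1)/(FPKM + 1)) over the 10631 genes with a mean of at least 1 FPKM over the 3 libraries, 9376 of them protein-coding. A gene was called higher or lower at an absolute log2 ratio of at least 1. With 1 library per group there was no test, no p-value and no standard error. Across genes the Pearson correlation of log2 values was 0.978 between the R280I libraries, 0.961 between the ATO libraries and 0.962 between wild-type ATO and R280I DMSO, and genes are not independent replicates.

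Before the data were examined, 30 gene lists were written, covering p53 targets, p53-repressed cell cycle genes, NRF2 and oxidative stress, metallothionein, heat shock, ATF4 targets, the unfolded protein response, NF-kB inflammatory genes, the interferon response, immediate-early genes, the BCL2 family, monocytes and macrophages, promyelocyte granules, progenitors, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, histones, DNA repair, iron and heme, arsenic transport and methylation, HLA class II and 5 other cell types. They hold 788 distinct genes, of which 787 were matched in the table and 541 passed the filter. Of the 63 measured p53 targets 8 stand on another list as well. The median of each list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The background held protein-coding genes with a unique symbol that passed the filter, and every list gene that passed. The members of the list itself were thus among the genes drawn from. This background and the minimum of 5 measured genes for this percentile were chosen after the data were examined.

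Named genes followed a rule fixed before the data were examined. It takes the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratio in each of the first 2 comparisons, up to 4 members with the largest ratio from each list, every p53 target past the fold limit, the p53 targets CDKN1A, MDM2, BBC3, BAX, TP53I3, GDF15, FAS, SESN1 and ZMAT3, and HMOX1, MT2A and HSPA1A. The levels of markers of other cell types were to be given as well. Some genes that the rule takes are not reported here, in text or figures, and they remain in the counts and list medians.

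The calculations were tested on simulated counts with 200 changed genes among 10604, with counting noise alone. For R280I ATO over R280I DMSO, 19 unchanged genes were called higher and 15 lower, 0 of them protein-coding, and 100% of genes changed 4-fold and 82% (higher) or 74% (lower) of those changed 2.5-fold were recovered. For wild-type ATO over R280I ATO the unchanged genes called were 16 and 21, with 98% of 4-fold and 78% of 2.5-fold changes recovered. For wild-type ATO over R280I DMSO they were 13 and 26, with 98% (higher) and 96% (lower) of 4-fold changes recovered. These numbers leave out the variation between cultures.

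The alternatives fixed in advance were pseudocounts of 0.1 and 5 FPKM, no filter, a filter at a mean of 5 FPKM, ratios centred on the median of all genes, a fold limit of 1.5 for p53 targets and the p53 list without its member of largest ratio. Protein-coding genes alone, centring within 10 classes of exon length and the p53 list without members of other lists were added after the data were examined. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.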

Results

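RNA was sequenced from U937 cells, a human myeloid malignant line of monocytic type, that expressed either wild-type p53 or p53-R280I, a form altered in the DNA-binding domain of this transcription factor. Cells expressing p53-R280I had received DMSO or 1 µg/mL ATO (arsenic trioxide, an arsenical used against acute promyelocytic leukaemia) for 24 h. Cells expressing wild-type p53 had received ATO for 24 h. Their dose was taken as 1 µg/mL, although the title of their library names none. Each of these 3 groups was represented by 1 library, so no difference given here has a replicate check, and no test between conditions was made. A wild-type library without ATO was not used here. The deposited values were FPKM per gene, and the depth recovered from their steps was about 18365800 reads for the R280I DMSO library, 18031700 for the R280I ATO library and 17645800 for the wild-type ATO library. Ranges in parentheses after a fold are 95% counting intervals, which cover counting error alone. Genes are called higher or lower where they differed at least 2-fold on the log2(FPKM + 1) scale, which understates differences of weakly expressed genes, whereas the folds of single genes are ratios of FPKM.

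The first comparison, of R280I cells with and without ATO, addressed whether p53 targets change with ATO in cells expressing the mutant protein. No library of cells without p53 was used. A change in a target therefore cannot be assigned to the mutant protein rather than to other responses to ATO. Among 63 measured p53 targets, BTG2, FUCA1 and CDKN1A were higher with ATO, and no member was lower. CDKN1A (ENSG00000124762, chromosome 6, positions 36676460 to 36687339 on GRCh38), which encodes the cyclin-dependent kinase inhibitor p21, was at 12.5 FPKM with DMSO and 27.6 FPKM with ATO, 2.21-fold higher (2.02 to 2.42). BTG2, an antiproliferative gene that is also an immediate-early gene, stood at 2.13 and 8.47 FPKM, 3.97-fold higher (3.21 to 4.95). FUCA1, which encodes a lysosomal fucosidase, was 2.33-fold higher (2.18 to 2.48), at 83.1 FPKM against 35.7.

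Most other p53 targets differed little between R280I cells with and without ATO. The list median was 0.04 on the log2 scale, with 40 of 63 members above 0, and lay at percentile 91.2 of 10000 random lists matched on expression, whose middle 95% ran from -0.07 to 0.06. MDM2, which encodes the ubiquitin ligase that degrades p53, was at 3.78 and 4.41 FPKM, a ratio of 1.17 (1.07 to 1.28). The proapoptotic genes BBC3 and BAX had ratios of 1.01 and 0.946 (0.846 to 1.06 for BAX), and the death receptor gene FAS stood at 0.329 and 0.355 FPKM. SESN1, a sestrin gene, had a ratio of 1.28 (1.00 to 1.63), and ZMAT3, an RNA-binding zinc finger gene, one of 1.44 (1.12 to 1.84). PLXNB2, a plexin gene, had a log2 ratio of 0.77. GDF15 and TP53I3 were under the filter on low values, at 0.159 and 0.384 FPKM with ATO.

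**Figure D1:**
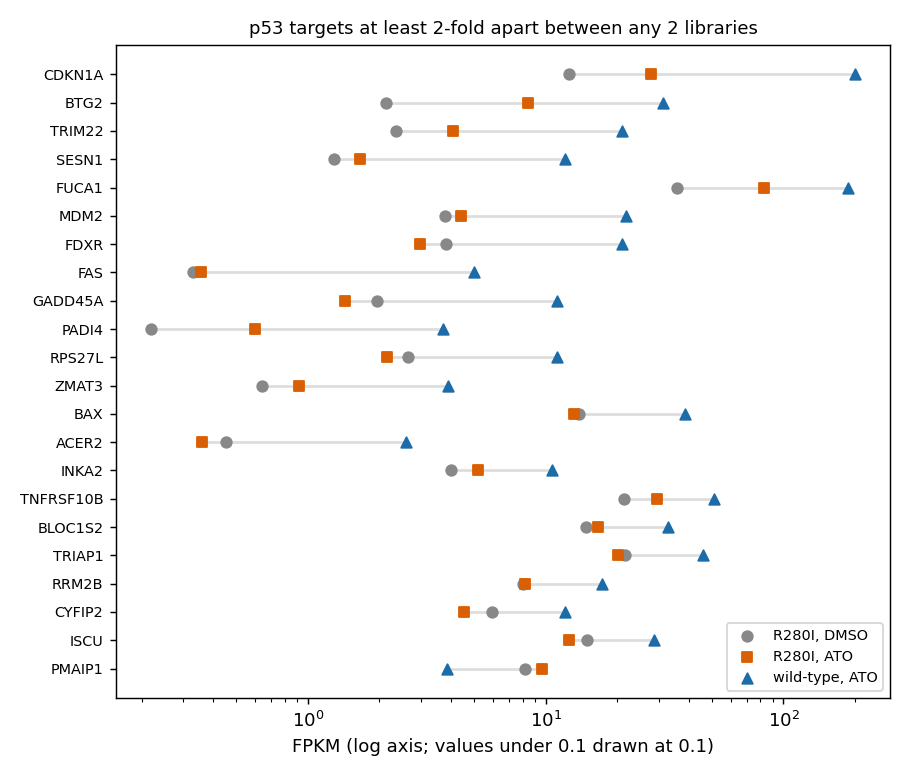
Levels of the 22 measured p53 targets that differed at least 2-fold between any pair of the 3 libraries, on a log axis of FPKM, with 1 point per library. CDKN1A, BTG2 and FUCA1 step upward from R280I DMSO through R280I ATO to wild-type ATO, whereas FAS, BAX and TRIAP1 have nearly the same level in both R280I libraries.

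Inflammatory genes and genes of monocytes and macrophages were the groups with the highest ratios in R280I cells given ATO. Of 18 measured targets of NF-kB, a transcription factor of inflammatory signalling, 10 were higher and 0 lower, with a list median of 1.11 that exceeded all random lists. CXCL8, which encodes the neutrophil chemoattractant interleukin-8, was at 6.59 FPKM with DMSO and 88.3 FPKM with ATO, 13.4-fold higher (11.9 to 15.2). TNFAIP3, a feedback inhibitor of NF-kB, was 7.34-fold higher (6.38 to 8.50), IER3 was 6.46-fold higher (4.80 to 8.91), and CCL2, which encodes a monocyte chemoattractant, was 5.77-fold higher (4.31 to 7.86). Of 28 measured monocyte and macrophage genes, 11 were higher and 0 lower, with a median of 0.78 that also exceeded all random lists. The calprotectin genes S100A8 and S100A9 were 8.68-fold (6.70 to 11.5) and 5.58-fold higher (5.00 to 6.23), with S100A9 at 36.7 and 204.6 FPKM. S100A12 was listed at 0 with DMSO and at 4.23 FPKM with ATO. It was 13.4-fold above a floor of 3 reads, and the lower limit of its counting interval was 10.5-fold.

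C3 (ENSG00000125730, chromosome 19, positions 6677704 to 6730562), the central complement component, had the highest log2 ratio among protein-coding genes, at 1.25 FPKM with DMSO and 43.2 FPKM with ATO, 34.4-fold higher (29.8 to 39.9). The interferon-inducible chemokine gene CXCL10 was at 0.185 and 16.5 FPKM, a ratio of 88.9 whose interval ran from 34.4 to 328 because the DMSO library held 4 reads. IL4I1, which encodes a secreted amino acid oxidase, was 16.3-fold higher (12.4 to 21.4), and ADAMDEC1, a metalloprotease gene of macrophages, was 8.66-fold higher (6.79 to 11.2). The NF-kB cofactor gene NFKBIZ was 7.34-fold higher (6.44 to 8.39). AQP9, a channel that also carries arsenite, was at 0.337 and 6.43 FPKM, 19.1-fold higher (12.2 to 31.6), and was the single member called higher among 6 measured genes of arsenic transport and methylation, whose median was -0.12 (0.0020 without a filter on low values). Of 16 interferon response genes 3 were higher, CXCL10, IFI6 and IFIH1, with a median of 0.44 (0.24 with a pseudocount of 5 or without a filter). Of 23 immediate-early genes 5 were higher, with a median also of 0.44, among them JUN at a ratio of 2.62 (2.42 to 2.83) and EGR1 at 2.60 (2.39 to 2.84). Both medians exceeded all random lists.

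Cholesterol synthesis genes, and with them a pair of fatty acid desaturase genes, were among the genes lowest with ATO in R280I cells. All 22 measured cholesterol synthesis genes had log2 ratios under 0, 5 were called lower, and their median of -0.64 lay under all random lists. INSIG1 (ENSG00000186480, chromosome 7, positions 155297776 to 155310235), a sterol-regulated brake on this pathway, was at 51.7 FPKM with DMSO and 14.4 FPKM with ATO, 3.59-fold lower (3.34 to 3.86). MSMO1 and DHCR7, enzymes of late sterol synthesis, were 3.11-fold (2.57 to 3.79) and 2.61-fold lower (2.33 to 2.91). ACAT2 was 2.17-fold lower (2.02 to 2.33), and the squalene synthase gene FDFT1 2.09-fold lower (2.0 to 2.19). The fatty acid desaturase genes FADS2 and SCD were 2.56-fold (2.41 to 2.72) and 2.26-fold lower (2.20 to 2.32), with SCD at 179 and 79.0 FPKM. Also among the 12 lowest were ACTL8 (4.79-fold), TMEM163 (2.79-fold), TENT5C (2.34-fold) and CST7, which encodes an inhibitor of granule cathepsins (2.19-fold, 2.03 to 2.36).

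**Figure D2:**
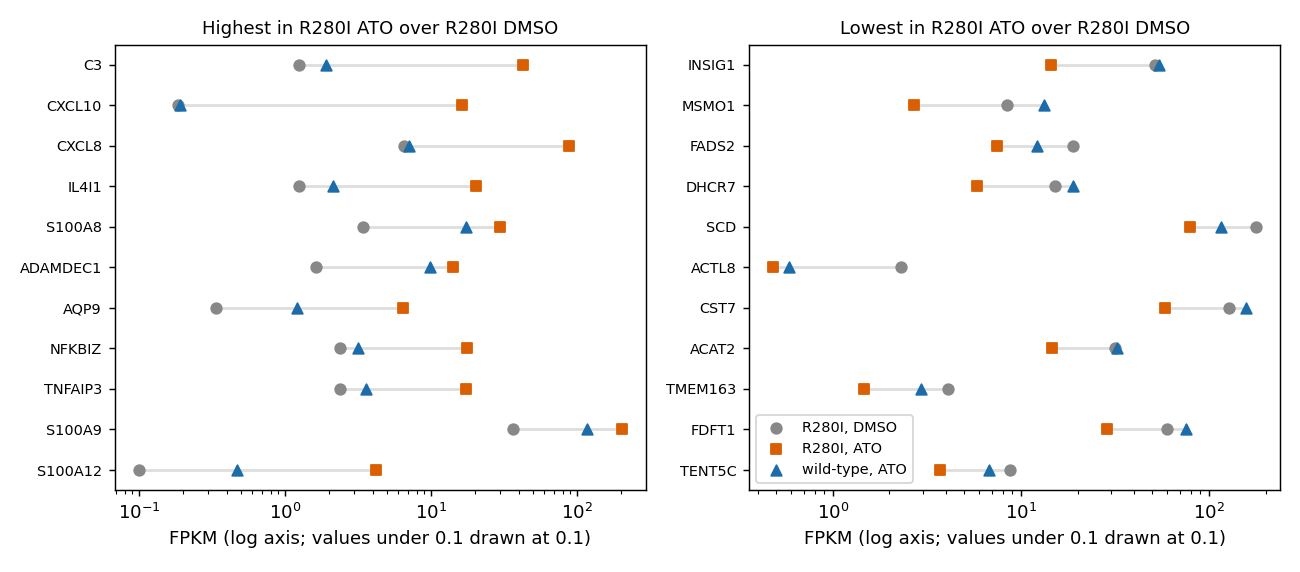
Levels of protein-coding genes among the 12 with the highest (left) and the 12 with the lowest (right) log2 ratio of R280I ATO over R280I DMSO, on log axes of FPKM, with 1 point per library. C3, CXCL10 and CXCL8 have similar levels in the wild-type ATO and R280I DMSO libraries, and so do INSIG1 and ACAT2. Others differ between these libraries, with S100A8, S100A9, ADAMDEC1 and AQP9 higher and FADS2, SCD and ACTL8 lower in wild-type ATO.

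Biosynthetic and proliferation genes were slightly lower as groups in R280I cells given ATO. All 23 ribosome biogenesis genes had log2 ratios under 0, with a median of -0.37. So did all 31 nuclear genes of oxidative phosphorylation, with a median of -0.23. Protein-coding genes in the shortest of 5 exon length classes also had a median slightly under 0, at -0.07. Under the alternatives, centring within length classes among them, the oxidative phosphorylation median ran from -0.24 to -0.18. The medians of 49 cell cycle genes that p53 represses, of 30 DNA repair genes and of 56 ribosomal protein genes were -0.18, -0.21 and -0.14. The last lay within the range of random lists, although 55 of 56 ribosomal protein genes were under 0. These random lists were drawn from a background that includes the ribosomal protein genes themselves. In these 5 groups of genes 0 members were called higher or lower. MCM7, which encodes a subunit of the replicative helicase, had a ratio of 0.601 (0.583 to 0.619). Of 12 promyelocyte granule genes CST7 alone was lower, and the median was -0.25, with the cathepsin G gene CTSG at 237 and 140 FPKM. The 9 measured progenitor genes had a median of -0.07, inside the random range.

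Most genes of the stress responses often linked to arsenic stayed within the fold limit. Of 20 NRF2 and oxidative stress genes FTH1 alone was higher, and the median was 0.08, at the edge of the random range. FTH1, the ferritin heavy chain gene, was at 35.9 and 115 FPKM, a ratio of 3.20 (3.01 to 3.41). It was likewise the single gene called higher of 15 iron and heme genes, whose median was 0.12, just above the random range. FTH1 has many processed pseudogenes, so its value is uncertain. HMOX1, which encodes heme oxygenase, had a ratio of 1.32 (1.17 to 1.48), the metallothionein gene MT2A one of 1.70 (1.62 to 1.77), and the heat shock gene HSPA1A one of 1.58 (1.04 to 2.48) at levels near 1 FPKM. The medians were 0.22 over 5 metallothionein and zinc response genes (0.019 without a filter) and -0.11 over 19 heat shock genes, both inside the random range. Unfolded protein response genes had a median of 0.09 over 22 genes, above that range. The median of 26 ATF4 targets was -0.20, under that range, with 17 members under 0, although CEBPB was called higher. The BCL2 family had a median of 0.18 over 13 genes, above the random range, with BCL2A1 2.20-fold higher (1.91 to 2.54). Glycolysis and hypoxia genes had a median of 0.04 over 21 genes, histone genes one of 0.07 over 8 (0 without a filter and 0.47 at a mean of at least 5 FPKM), mitochondrially encoded genes one of 0.14 over 13 and HLA class II genes one of 0.77 over 3. The mitochondrially encoded median lay above the random range, and the glycolysis and histone medians inside it.

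Over all 10631 genes that passed the filter, 130 were higher and 57 lower with ATO in R280I cells. Among protein-coding genes the split was 80 to 11, and of the other 50 higher and 46 lower genes, 33 and 38 rested on fewer than 20 reads. Under the alternatives tried, the counts ran from 37 to 226 higher and from 5 to 122 lower genes, and the p53 targets called higher from 1 to 6. Of 24 lists with at least 5 measured genes, 16 had a median outside the middle 95% of random lists, against 1.2 for random lists, and since genes of a list are regulated together these percentiles only describe the libraries.

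The second comparison set the wild-type ATO library against the R280I ATO library and addressed how the lines differed when both had received ATO. p53 targets were higher as a group. The list held 86 targets, of which 63 passed the filter. Of these 63, 17 were higher with wild-type p53, 1 was lower and 54 had log2 ratios above 0. Their median of 0.66 exceeded all random lists. GDF15 and TP53I3, under the filter, stood at 0.353 and 0.221 FPKM with wild-type p53, against 0.159 and 0.384 FPKM with p53-R280I. CDKN1A was at 200.5 FPKM with wild-type p53 and 27.6 FPKM with p53-R280I, 7.25-fold higher (6.87 to 7.66). MDM2 (ENSG00000135679, chromosome 12, positions 68808176 to 68850686) was at 21.8 and 4.41 FPKM, 4.94-fold higher (4.62 to 5.28).

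Targets with functions in apoptosis, growth arrest and metabolism were among those higher with wild-type p53. The apoptosis genes FAS and BAX were 14.1-fold (9.62 to 21.9) and 2.94-fold higher (2.68 to 3.23). BBC3 was at 3.65 and 1.67 FPKM, 2.18-fold higher as a ratio (1.70 to 2.81) but short of the limit on the log2 scale. GADD45A, a growth arrest gene induced by DNA damage, was 7.75-fold higher (5.79 to 10.4), and FDXR, which encodes ferredoxin reductase, 7.07-fold higher (6.07 to 8.27). SESN1 was 7.25-fold higher (6.13 to 8.66), ZMAT3 4.22-fold (3.54 to 5.03), TRIM22 5.12-fold (4.62 to 5.67), BTG2 3.67-fold (3.29 to 4.10) and FUCA1 2.25-fold (2.15 to 2.35). ACER2, CYFIP2, ISCU, PADI4, RPS27L and TRIAP1 completed the 17. PMAIP1, which encodes the proapoptotic protein NOXA, went the other way, at 3.86 FPKM with wild-type p53 and 9.62 FPKM with p53-R280I, 2.49-fold lower (2.06 to 3.03).

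Of the 12 protein-coding genes highest with wild-type p53, 5 were on the p53 list. The other 7 were CHCHD10, a mitochondrial intermembrane space gene (10.6 and 90.1 FPKM, 8.50-fold, 7.47 to 9.71), ELOB, the elongin B gene (7.88-fold, 6.93 to 9.0), CWC27, a spliceosome gene (13.5-fold, 10.2 to 18), ENDOG, a mitochondrial nuclease gene (6.65-fold, 4.95 to 9.19), ERLEC1 (5.86-fold, 5.00 to 6.87), FAM98A (5.53-fold, 4.99 to 6.16) and SIGLEC14 (5.52-fold, 4.51 to 6.80). The levels of these 7 genes in the R280I DMSO library were within 2-fold of those in the R280I ATO library, for example 10.3 FPKM for CHCHD10 and 15.6 against 12.9 FPKM for ELOB. No measured protein-coding gene within 500 kb of any of the 12 was called higher, and FAM98A had no such neighbour. Genes of other types were not looked at. SIGLEC14 has a near-identical paralog, and how shared reads were counted was not given in the sources used here.

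Inflammatory and immediate-early genes were lower with wild-type p53 than with p53-R280I under ATO. Of 18 NF-kB targets 10 were lower and 0 higher, with a median of -1.22, and of 23 immediate-early genes 9 were lower and BTG2 was higher, with a median of -0.84. Both medians lay under all random lists. C3 was 22.6-fold (20.03 to 25.5), CXCL10 85.4-fold (33.1 to 315), CXCL8 12.5-fold (11.1 to 14.2) and IL4I1 9.49-fold (7.66 to 11.8) lower. EGR1, an immediate-early transcription factor, was at 2.28 FPKM against 34, 14.9-fold lower (12.5 to 18), and DUSP1, a phosphatase gene of the same list, 5.21-fold lower (3.92 to 7.08). IER3 and CCL2 were 11.9-fold (8.02 to 18.6) and 11.5-fold lower (7.71 to 17.9), and TNF, NFKBIA and NFKBIZ were 6.06-fold (4.43 to 8.47), 5.35-fold (4.73 to 6.07) and 5.54-fold lower (4.92 to 6.24). C5AR1, the receptor gene for complement fragment C5a, was 7.45-fold lower (5.92 to 9.40). The HLA class II gene HLA-DRA was 17.3-fold lower (9.17 to 39.7), and 2 of 3 measured genes of that list were lower, with a median of -1.01. Interferon response genes had a median of -0.50, with 2 of 16 lower, and the median was -0.15 both without a filter on low values and with one at a mean of 5 FPKM.

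Monocyte and macrophage genes differed less between the lines. Their median was -0.27, still under all random lists, with 20 of 28 members under 0. Of the 28, 3 were called lower, among them S100A12 and CSF1R. CSF1R, the receptor gene for macrophage colony-stimulating factor, was 5.05-fold lower (4.20 to 6.12). Promyelocyte granule genes were higher with wild-type p53 in 5 of 12 cases, with a median of 0.84 and all 12 above 0. CEACAM8 was 8.28-fold higher (5.92 to 11.9), CST7 2.71-fold (2.52 to 2.92), RNASE3 2.57-fold (2.46 to 2.70) and the neutrophil elastase gene ELANE 2.27-fold (2.19 to 2.35).

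Cholesterol synthesis genes were higher in the wild-type library, 8 of 22 by the fold limit, with a median of 0.88. MSMO1 was 4.90-fold higher (4.08 to 5.92), INSIG1 3.76-fold (3.50 to 4.05), DHCR7 3.26-fold (2.93 to 3.64) and FDFT1 2.62-fold (2.51 to 2.74). ATF4 targets, which serve amino acid supply, were lower in 4 of 26 cases, with a median of -0.66. The serine synthesis genes PSAT1 and PHGDH were 3.62-fold (3.40 to 3.85) and 3.24-fold lower (3.08 to 3.41), ATF5 was 2.77-fold lower (2.53 to 3.04) and PCK2 2.11-fold lower (1.96 to 2.28). Of 20 NRF2 genes 3 were higher, with a median of 0.39 (0.099 without a filter on low values). The 3 were PIR (3.28-fold, 2.51 to 4.32), GCLM, a subunit gene of a ligase in glutathione synthesis (2.61-fold, 2.33 to 2.93), and HMOX1 (2.29-fold, 2.09 to 2.51). MT2A was 2.65-fold lower with wild-type p53, the single member called lower of 5 metallothionein and zinc response genes, whose median was -0.07. Heat shock genes had a median of 0.33, with HSPA1B and HSPA8 of 19 called higher, and HSPA1A was 2.01-fold higher (1.45 to 2.81). HSPA1A and HSPA1B are near-identical copies, so the division of reads between them is uncertain.

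Cell cycle genes that p53 represses were lower as a group with wild-type p53, with a median of -0.39, 45 of 49 members under 0 and 0 past the fold limit. PLK4, E2F2 and E2F1 had ratios of 0.50 (0.450 to 0.556), 0.530 (0.482 to 0.582) and 0.607 (0.544 to 0.677). DNA repair and progenitor genes had medians of -0.27 and -0.37, with 0 members called in either, and the progenitor median was 0.00019 without a filter on low values. The BCL2 family (median 0.12, or 0.015 at a mean of at least 5 FPKM, with BAX and BIK higher and PMAIP1 lower), unfolded protein response genes (-0.12, with PDIA3 higher), ribosome biogenesis genes (0.12, with GAR1 higher), iron and heme genes (0.10, with HMOX1 higher), glycolysis and hypoxia genes (-0.07, or 0.0056 after the length centring described next, with NDRG1 and VEGFA lower) and arsenic transport genes (-0.05, with AQP9 lower) all had medians inside the random range. Mitochondrially encoded genes had a median of -0.16 (-0.38 after length centring), under that range.

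The 2 ATO libraries also differed along exon length. Across 9376 protein-coding genes, which are not independent replicates, the Spearman correlation of the log2 ratio with exon length was -0.28, and class medians ran from 0.16 in the shortest class of 5 to -0.16 in the longest. Ribosomal protein genes, nuclear genes of oxidative phosphorylation and histone genes are short, and their medians of 0.32, 0.40 and 0.69 became 0.27, 0.30 and 0.47 when ratios were centred within 10 length classes, an alternative added after the data were examined. Without a filter on low values, which 8 of 45 histone genes passed, the histone median was 0.0058. The promyelocyte granule median became 0.62. Of the 8 measured histone genes 3 were higher, H2BC11, H2AC13 and H3C10, each under 5 FPKM.

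**Figure D3:**
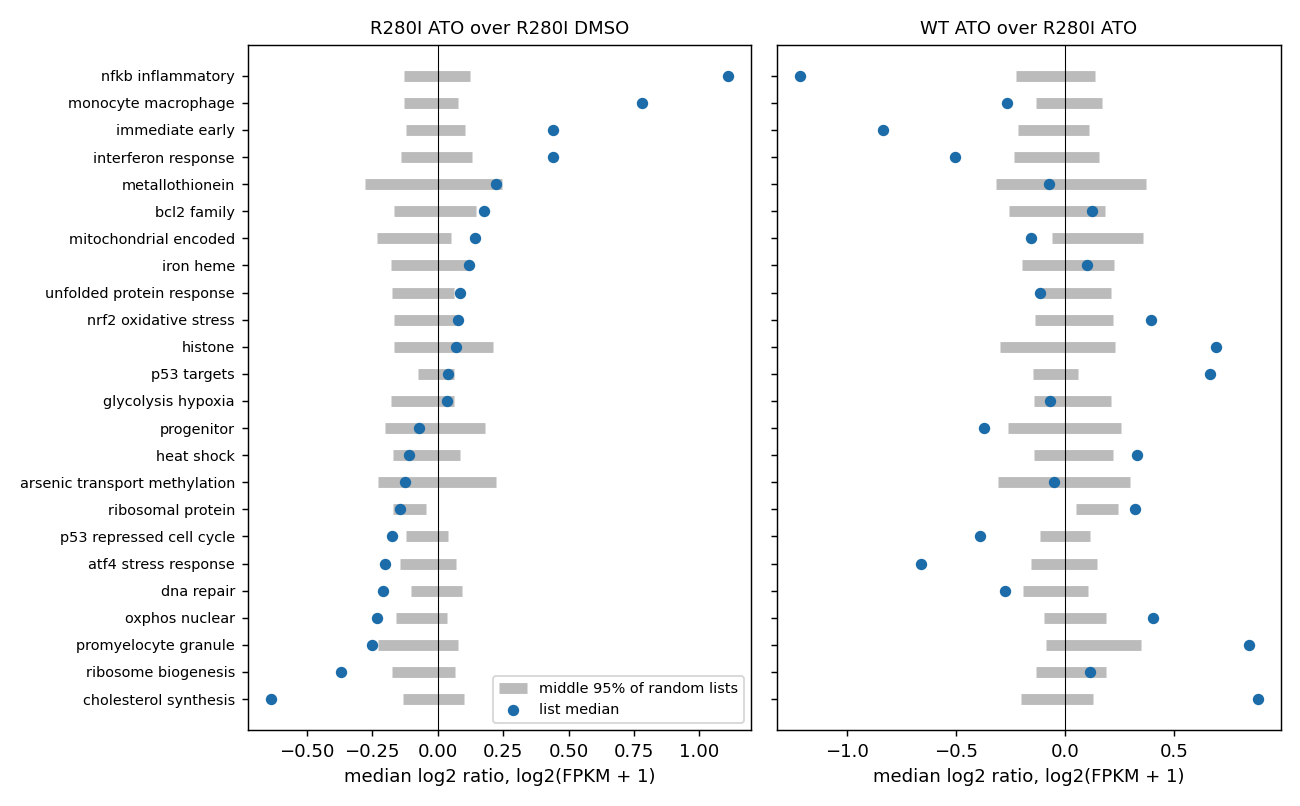
Median log2 ratio of each of the 24 gene lists with at least 5 measured genes (points) and the middle 95% of 10000 random lists matched on expression (grey bars), for R280I ATO over R280I DMSO (left) and wild-type ATO over R280I ATO (right). NF-kB inflammatory genes have medians of 1.11 and -1.22, cholesterol synthesis genes -0.64 and 0.88, and p53 targets 0.04 and 0.66.

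Over all genes that passed the filter, 243 were higher and 149 lower with wild-type p53, and among protein-coding genes 146 and 85. Under the alternatives these counts ran from 76 to 386 and from 37 to 275, and the p53 targets called higher from 11 to 37. The R280I ATO library enters both comparisons with opposite sign, so a value that is high or low in that library alone gives ratios of opposite sign in them.

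The wild-type ATO library was also set against the R280I DMSO library, a comparison in which p53 form and treatment differ together. Each log2 ratio in it is the sum of the gene's ratios in the first and second comparisons, so it is not a separate observation. Of 63 p53 targets 19 were higher and 0 lower, with a median of 0.68. CDKN1A was 16-fold (14.8 to 17.3), BTG2 14.6-fold (12 to 17.9), TRIM22 8.91-fold (7.84 to 10.2) and FUCA1 5.23-fold higher (4.93 to 5.55). Monocyte and macrophage genes were higher in 13 of 28 cases, with a median of 0.83, against 0.78 for R280I ATO over the same DMSO library. Without a filter on low values these medians were 0.28 and 0.62. NCF1 was 9.94-fold (8.67 to 11.5), S100A8 5.07-fold (3.87 to 6.78) and CYBB, the catalytic subunit gene of the phagocyte oxidase, 4.46-fold higher (3.86 to 5.15). NCF1 has near-identical pseudogenes, so its value is uncertain. NF-kB targets had a median of 0.07, inside the random range, with 1 of 18 higher and 1 lower, and CXCL8 had a ratio of 1.07 (0.904 to 1.27).

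Also in this comparison, ATF4 targets were lower in 9 of 26 cases, with a median of -0.92, and PSAT1 was 5.46-fold lower (5.15 to 5.80). Cell cycle and DNA repair genes had medians of -0.58 and -0.50 with 0 members called, and NRF2 genes one of 0.54 (0.17 without a filter), with HMOX1 3.02-fold higher (2.73 to 3.35). Cholesterol synthesis genes had a median of 0.19 with 0 of 22 called. Over all genes 280 were higher and 103 lower, and among protein-coding genes 189 and 43, with ranges over the alternatives of 98 to 455 and 21 to 228. Because both ATO libraries were set against 1 DMSO library, ratios that look alike in the comparisons with it can share the counting error and handling of that library.

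Markers of other cell types were low in all 3 libraries. Of 65 markers of T and B lymphoid, erythroid and megakaryocytic, epithelial and fibroblast cells, 6 reached 1 FPKM in the R280I DMSO library, 8 in the R280I ATO library and 6 in the wild-type ATO library. The exception in level was CD4, which monocytes also express, at 132, 172 and 183 FPKM. The highest B lymphoid, fibroblast, erythroid and epithelial markers with ATO in R280I cells were CD79A at 1.94, FAP at 1.76, KLF1 at 1.41 and MUC1 at 1.71 FPKM. Mitochondrially encoded genes took 21.4%, 23.4% and 19.6% of the FPKM total in the R280I DMSO, R280I ATO and wild-type ATO libraries, and the 10 highest genes 20.2%, 22.5% and 20.5%.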

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

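Protein-coding genes alone, centring within exon length classes and the p53 list without members of other lists were chosen after the data were examined, and the other alternatives before. Over 457 results and 3073 alternatives, 2667 values stayed within their counting or list interval, or within 1.5 times for counts. Another 405 moved further. Signs changed in 8 of 510 alternatives for lists and 7 of 2473 for genes, with 0 of them for a gene called higher or lower. The single list outside the random range whose sign changed was the progenitor list in wild-type ATO over R280I ATO, at 0.00019 without a filter, which adds members near 0 FPKM, against -0.37. Centring subtracted median ratios of -0.01, -0.03 and -0.03, which moved the ratios slightly upward. No paired analysis was possible because each group held 1 library, and no library could be left out.

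Counts of genes moved with the pseudocount, the filter and the restriction to protein-coding genes. For R280I ATO over R280I DMSO, the 130 higher genes became 226 with a pseudocount of 0.1, 37 with one of 5, 202 without a filter, 58 with a mean of at least 5 FPKM and 80 among protein-coding genes. The 57 lower genes became 122, 5, 120, 12 and 11 in that order, and 12 after length centring of protein-coding genes. For wild-type ATO over R280I ATO, the 243 higher genes became 386 with a pseudocount of 0.1, 76 with one of 5, 117 with a mean of at least 5 FPKM, 146 among protein-coding genes and 126 among protein-coding genes with length centring, and the 149 lower genes became 275, 37, 68, 85 and 92. For wild-type ATO over R280I DMSO, the 280 higher genes became 455, 98, 146 with a mean of at least 5 FPKM and 180 among protein-coding genes with length centring, against 189 among protein-coding genes without it. The 103 lower genes became 228, 21, 164 without a filter, 42 with a mean of at least 5 FPKM, 43 among protein-coding genes and 40 among these with length centring. The filters differ in how many genes they admit, 24112 without one and 6489 at a mean of 5 FPKM.

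A pseudocount of 5 shrinks ratios by its construction. It gave list medians of 0.78 for NF-kB targets, 0.60 for monocyte and macrophage genes and -0.14 for cell cycle genes in R280I ATO over R280I DMSO, 0.43 for p53 targets and 0.67 for cholesterol synthesis genes in wild-type ATO over R280I ATO, and 0.45 for p53 targets in wild-type ATO over R280I DMSO. Without a filter the monocyte median was 0.62 in the first comparison and the p53 medians were 0.45 and 0.50 in the other two. In wild-type ATO over R280I DMSO the lack of a filter moved the monocyte median from 0.83 to 0.28, the NRF2 median from 0.54 to 0.17, the progenitor median from -0.44 to -0.14 and the histone median from 0.84 to 0.0038. In wild-type ATO over R280I ATO it moved the NRF2 median from 0.39 to 0.099, the interferon response median from -0.50 to -0.15 and the histone median from 0.69 to 0.0058, and a mean of at least 5 FPKM also gave -0.15 for the interferon response. In R280I ATO over R280I DMSO the interferon response median of 0.44 became 0.24 with a pseudocount of 5 or without a filter. In wild-type ATO over R280I DMSO a pseudocount of 5 gave 0.47 for monocyte and macrophage genes and 0.38 for histone genes. Length centring, always of protein-coding genes alone, gave -0.15 for cell cycle genes in the first comparison, and the cause was not tested. The p53 targets called higher numbered 6, 37 and 39 at a fold limit of 1.5 in the 3 comparisons, against 3, 17 and 19. With a pseudocount of 5 they numbered 1, 11 and 11, with one of 0.1 they numbered 5 in the first comparison, and with a mean of at least 5 FPKM they numbered 11 in the second. Depth limits genes under about 20 reads, which made up 33 of the 130 higher and 38 of the 57 lower genes in R280I ATO over R280I DMSO.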

Other observations

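In wild-type ATO over R280I DMSO, in which p53 form and treatment differ together, further gene groups stood apart from random lists. Iron and heme genes had a median of 0.32 (0.18 with a pseudocount of 5), with 4 of 15 called higher, HMOX1, FTH1, FTL and ALAS1. ALAS1, the first enzyme gene of heme synthesis, was at 88.1 FPKM with R280I DMSO, 174 FPKM with R280I ATO and 186 FPKM with wild-type ATO, and was 2.11-fold higher (2.03 to 2.19) in the last than in the first. The ferritin light chain gene FTL was 2.23-fold higher (2.21 to 2.25). Promyelocyte granule genes had a median of 0.45, with 4 of 12 higher, among them CEACAM8 at a ratio of 8.02 (5.78 to 11.4), AZU1 at 2.38 (2.30 to 2.46) and the serglycin gene SRGN at 2.16 (2.14 to 2.19). Immediate-early genes had a median of -0.40 (-0.23 with a pseudocount of 5) and progenitor genes one of -0.44 (-0.14 without a filter on low values), and MYC, on both lists, was at 67.1, 43.3 and 33.3 FPKM in the same order of libraries. The BCL2 family had a median of 0.29, with BCL2A1 2.85-fold higher (2.48 to 3.27), and 4 of 8 histone genes were higher, with a median of 0.84. The histone median was 0.0038 without a filter on low values, which 8 of 45 genes passed. The pseudocount holds ratios of genes near 0 FPKM close to 0. The median without a filter therefore cannot show whether the other histone genes differed.

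In what follows, the tests of exon length were fixed before their results were seen, except that of the inflammatory list between the ATO libraries, which was chosen after. All were run on the libraries in which the patterns were noticed, so each explanation is a hypothesis.

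The length difference between the ATO libraries was examined as a source of the higher p53 targets with wild-type p53 than with p53-R280I. After centring within 10 exon length classes the list median was 0.762 (order-statistic interval 0.524 to 0.850), above the random range of -0.094 to 0.090. Before centring it was 0.66. Of 63 members 16 passed the fold limit, against 17 before. The median did not fall with centring, which argues against length as a cause of the higher list median. A difference in p53 activity or in the amount of p53 protein, which was not measured, a difference between the lines unrelated to p53 and the handling of a single library stay open, and 7 of the 12 highest genes were on no p53 list used here. No wild-type library without ATO was used, so how much of the difference needs ATO was not tested.

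As a group, the inflammatory genes were higher in the R280I ATO library than in the other two, with BCL2A1 an exception that was higher over R280I DMSO in both ATO libraries. In R280I ATO over R280I DMSO, where the length trend was slight, with class medians from -0.07 to 0.02, length centring left their median at 1.15 (0.817 to 1.67), with 11 of 18 past the fold limit, against a random range of -0.119 to 0.131. In wild-type ATO over R280I ATO, where the trend was larger, it left -1.10 (-1.997 to -0.673), with 10 of 18 past the limit, against -0.178 to 0.156. Both argue against length as the whole cause. A candidate explanation that stays open is an inflammatory response to ATO that depends on the p53 form, and so do a difference between the lines and the state of 1 culture at harvest. A part in a monocyte-type change was not tested. Over R280I DMSO, monocyte and macrophage genes had medians of 0.78 with R280I ATO and 0.83 with wild-type ATO (0.62 and 0.28 without a filter). NF-kB targets had medians of 1.11 and 0.07 in the same order. Higher monocyte genes thus came without higher NF-kB targets in the wild-type ATO library.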
